A study of Mus musculus with 12 samples.

How the data were processed

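Total RNA from 12 cell samples was profiled, 1 array each, in 4 groups of 3. The groups were RAW264.7 cells, a mouse macrophage-like line, carrying a control vector or a short hairpin RNA against Abhd5, and CT-26 cells, a mouse colon carcinoma line, primed by one or the other kind of RAW264.7 cell. The labels do not say how priming was done, whether CT-26 cells were separated from RAW264.7 cells before RNA extraction, or whether the 3 samples of a group came from separate cultures. The p-values therefore measure the spread between these samples only.

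Per the labels, RNA was extracted with TRIzol, amplified and labelled with Cy3. Per the file headers, the 1-colour Agilent mouse expression arrays were read with Agilent Feature Extraction 10.7.3.1, and the probe coordinates in the files are of the mm9 build. Per the file headers, the deposited scanner files hold the intensity of each spot on a linear scale. They give a processed signal, which the software had corrected for background within the array without scaling between arrays, and the uncorrected mean and local background signals. The deposited table of processed values did not state its scale, so each of its columns was set against the scanner signals. As deposited by the authors, the 6 RAW264.7 columns held log2 values of the processed signal, normalized by subtracting the array's 75th percentile; this was read from the values, since the labels state no method. Each matched its own scanner file, with column medians of -3.81, -3.53 and -3.90 for control replicates and -4.02, -3.94 and -3.93 for knockdown replicates. The 6 CT-26 columns held linear intensity values as deposited by the authors, with medians of 272.6, 276.02 and 274.4 for control-primed and 226.1, 131.7 and 174 for knockdown-primed replicates. Of these 1 matched its own scanner file, and 5 matched another replicate of the same group. That table was used only as an alternative.

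The slide of each array was read from the files. Slide 1 held RAW264.7 control replicates 1 and 2, slide 2 held RAW264.7 control replicate 3 and all 3 knockdown arrays, and slide 3 held all 6 CT-26 arrays. Each slide had a scan of its own, so slide and scan could not be separated.

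Each array held 59305 spots that were not controls, for 55681 different probes. Control spots (3671 per array) and spots with an outlier flag (172 to 272 per array) were left out, and no spot was saturated. Signals were put on the log2 scale, the array's 75th percentile was subtracted, and spots of the same probe were averaged. Gene names came from accessions in the files through a RefSeq gene table (assembly GRCm38.p6, used for names only) for 26762 probes and through the symbol for 3819; 25100 probes kept the name of the array design. This gave 35080 names, of which 27074 had a probe well above background on all 3 arrays of a group. The brightest such probe over all 12 arrays stood for its gene. A gene was tested in a comparison if that probe was well above background on all 3 arrays of either group.

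Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. The RAW264.7 comparison used its 6 arrays and the CT-26 comparison the other 6. The difference between the comparisons was an interaction contrast over all 12 arrays. Log2 changes are knockdown minus control, or knockdown-primed minus control-primed, with the standard error of the fit (SE) and n = 3 per group. Where a gene was well above background on all arrays of 1 group and none of the other, the fold is a lower bound: the mean of the detected group against a mean, in the other, of the higher of the probe's own signal and the array's lowest signal well above background. A gene counted as below background only if all its probes were. The number of arrays limits the precision of every value.

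Before the data were examined, 25 gene lists, the alternatives and the rule for named genes were fixed. Lists were tested against all other tested genes with limma's camera, with a preset correlation of 0.01 between genes and, beside it, an estimated correlation, both adjusted over the 25 lists; members were also counted after adjustment over the list alone. Named genes were Abhd5, the 8 largest rises and 8 largest falls per cell line among genes past the threshold that were well above background on all 6 arrays and whose groups did not overlap, up to 3 genes per direction detected in only 1 group, up to 4 members of each list with the smallest p, and the 5 largest differences between cell lines per direction. Predicted and clone names were passed over (7 among the CT-26 falls). One departure was made after the values were seen: taken literally, the rule would have filled the 8 CT-26 falls with features that carry no gene symbol, so 18 such features were passed over there, 1 among the CT-26 rises, 2 among the CT-26 genes detected in control-primed cells only, and 1 among the RAW264.7 genes detected in control cells only. The results of 2 genes that the rule names are not reported here.

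The fits were tested on simulated data in which 100 genes were changed by 1 and 100 by 2 on the log2 scale. The RAW264.7 fit recovered 12% and 73% of them among 25394 genes with 3 false calls, the CT-26 fit 36% and 88% among 24930 genes with 2, and the fit of the difference 21% and 81% among 23254 genes with 5. Camera called the 1 shifted list and none of 20 unshifted ones. The simulated genes varied independently and carried no slide effect, so these numbers do not cover calls that come from correlated genes or from the slide.

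Alternatives were normexp background correction with an offset of 50, quantile normalisation, median centring, no filter or a stricter filter on detection, keeping outlier flags, the mean of a gene's probes, each probe on its own, an intensity trend, array weights, a fit of all 12 arrays, the replicate number as a block, the slide as a block, the deposited table, a 2-fold minimum, and each array left out in turn. A fit of the 4 arrays of slide 2 alone, the slide as a random block, and the lists within the slide were added after seeing the data.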

Results

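The series asked how silencing Abhd5 changed gene expression in RAW264.7 macrophages and in CT-26 tumour cells primed by those macrophages. Spots well above background made up 56.5% and 57.9% on RAW264.7 control replicates 1 and 2 (slide 1), 72.7% on control replicate 3 and 71.2%, 73.0% and 69.0% on the knockdown arrays (all slide 2). On the CT-26 arrays they made up 73.0%, 77.3% and 68.3% after priming by control cells and 67.0%, 63.8% and 59.3% after priming by knockdown cells (all slide 3). Replicates of a group correlated between 0.979 and 0.995 across probes.

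Abhd5 encodes a co-activator of the lipase ATGL, which releases fatty acids from lipid droplets, and its level checks the labels of the knockdown. In RAW264.7 cells it fell from a log2 level of 1.60 ± 0.28 to 0.28 ± 0.09 (SD, n = 3, relative to the array's 75th percentile), a change of -1.32 ± 0.20 (SE, limma adjusted p = 0.00342) that left 40% of the control level. The probe lies at chromosome 9, 122288857 to 122288916 (mm9). A second probe (122277200 to 122277259) gave -1.29, and the third (122289983 to 122290042), a dimmer one, gave -0.78 with an adjusted p of 0.0774 over probes. With the slide as a block the change was -1.24 (adjusted p = 0.0541), so the call was lost. Among the 4 arrays of slide 2, a fit added after seeing the data, it was -1.24 (limma adjusted p = 0.0174), but there the single control array is assumed to vary like the knockdown arrays, and that p does not restore the call. In CT-26 cells the change was 0.06 ± 0.155 (95% interval -0.285 to 0.414, adjusted p = 0.799), while the other 2 probes gave -0.49 and -0.31, neither past the threshold.

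**Figure D1:**
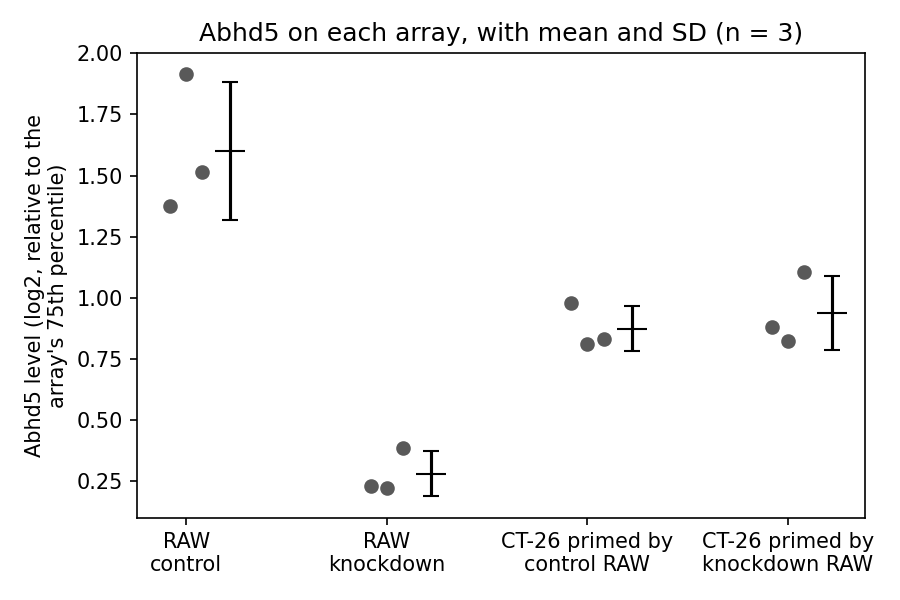
Abhd5 level on each of the 12 arrays (log2, relative to the array's 75th percentile), with the mean and SD of each group (n = 3). The 3 RAW264.7 knockdown arrays lie below the 3 control arrays, with means of 0.28 and 1.60.

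Among genes well above background on all 6 RAW264.7 arrays, the largest rises after Abhd5 knockdown included several inflammatory genes. The cytokine Il1b rose by 6.80 ± 0.28 on the log2 scale (111.2-fold), S100a8, a subunit of calprotectin, by 6.41 ± 0.37, the monocyte chemoattractant Ccl2 by 6.30 ± 0.20, and the myeloid receptor gene Trem3 by 6.07 ± 0.32. Ppfibp2, of the liprin family, rose by 6.30 ± 0.22, the chemokine Pf4 by 5.66 ± 0.21, the membrane protein gene Ms4a6d by 5.60 ± 0.20, and Pdpn, which encodes podoplanin, by 5.42 ± 0.21. The bone-resorbing protease cathepsin K (Ctsk) was at least 323-fold higher, and the chemokines Ccl7 and Cxcl3 at least 283-fold and 164-fold higher, since control arrays held no signal well above background for them. The adjusted p of these 11 genes lay at 2.18e-05 or below. After normexp the log2 changes of Ctsk, Ccl7 and Cxcl3 were 7.48, 6.96 and 6.92, smaller than their bounds.

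The largest falls were those of Tmem26 (-5.51 ± 0.22), the small heat shock protein gene Hspb7 (-5.33 ± 0.22), the adaptor gene Hsh2d (-4.91 ± 0.23) and Pxdn, which encodes a matrix peroxidase (-4.85 ± 0.21). The RNA-binding protein gene Igf2bp1 followed (-4.39 ± 0.18), with the phospholipase gene Gdpd3 (-4.29 ± 0.17), the homeobox gene Hoxc6 (-4.20 ± 0.20) and Myadml2 (-3.71 ± 0.30). Detected in control cells alone were Odf3l1, at least 14.5-fold lower after knockdown, the B-cell transcription factor Ebf1, at least 3.8-fold, and the olfactory receptor gene Olfr52, at least 3.71-fold. Against the single control array of slide 2, all 16 of the largest rises and falls kept their direction, but Ebf1 and Olfr52 changed by -1.15 and -1.06, less than the bounds from all 3 controls. A second Pxdn probe gave -2.49. After normexp the log2 changes of Odf3l1, Ebf1 and Olfr52 were -2.93, -1.27 and -1.31, smaller in size than their bounds.

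Of 25460 genes tested in RAW264.7 cells, 5856 changed, 2022 higher and 3834 lower, and 2561 did so by at least 2-fold (1420 higher, 1141 lower). The median change of all tested genes was -0.302 in this scaling, -0.08 with median centring, -0.0974 after quantile normalisation and -0.366 after normexp. The split of calls moved with it, to 2409 higher and 1414 lower, 2155 and 2016, and 1745 and 5817. At 2-fold or more it was 1701 and 453, 1497 and 570, and 956 and 892. There rises were the larger part in each scaling, by margins that differed widely, while the larger part of all calls changed with the scaling. With the slide as a block 1173 genes passed (893 higher, 280 lower), 1113 of them among the 5856, and on slide 2 alone, with 1 control array, 1857 did (1208 higher, 649 lower). Leaving out 1 array gave between 1704 genes (without knockdown replicate 3) and 7389 (without control replicate 3), with 1976 and 2688 without knockdown replicates 2 and 1 and 2850 without control replicate 1.

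Among targets of NF-kB, 19 of 36 tested members rose and none fell in RAW264.7 cells (23 and 0 adjusted over the list alone; 12 with the slide as a block). Ccl2, Il1b, Ccl7 and Cxcl3 had the smallest p. Camera placed the list above the other genes (adjusted p = 8.86e-18), a call that was lost with an estimated correlation (adjusted p = 0.0833). Inflammasome genes showed 7 rises and no fall among 17 (8 and 0 adjusted over the list alone; 4 with the slide as a block), led by Il1b, the receptor antagonist Il1rn (4.02 ± 0.22), the sensor Nlrc4 (2.85 ± 0.27) and the channel gene Panx1 (1.26 ± 0.20). The list's adjusted p was 2.95e-07, and adjusted p = 0.0833 with an estimated correlation.

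Genes of alternative macrophage activation rose together with the inflammatory ones. Of 19 tested, 12 rose and 2 fell (14 and 4 adjusted over the list alone; 10 rises and no fall with the slide as a block), with an adjusted p of 5.14e-09 and 0.0341 with an estimated correlation. The scavenger receptor Cd36 rose by 3.28 ± 0.25, the cytokine Il10 by 2.32 ± 0.21, and the endocytic receptors Clec10a and Stab1 by 2.47 ± 0.23 and 1.97 ± 0.19. Osteoclast genes showed 9 rises and no fall among 16 (10 and 0 adjusted over the list alone; 6 with the slide as a block; adjusted p = 5.14e-09, and 0.0341 with an estimated correlation). Among them the proton pump subunit Atp6v0d2 was at least 79.9-fold higher (fitted changes of 8.07 and 4.86 for its 2 probes), Ctsk at least 323-fold, the gelatinase Mmp9 rose by 7.08 ± 0.29, and Acp5, the tartrate-resistant acid phosphatase, by 4.01 ± 0.18. These were the 2 lists whose camera call held with an estimated correlation.

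Matrix metalloproteinases and their inhibitors moved both ways in RAW264.7 cells, with 9 rises and 2 falls among 18, the same adjusted over the list alone, and 7 and 1 with the slide as a block (adjusted p = 0.000208, and 0.279 with an estimated correlation). Mmp9 led, the collagenase Mmp13 was at least 7.14-fold higher, and of the inhibitors Timp1 fell by 2.53, while the brightest Timp2 probe rose by 2.45 ± 0.22 and its other probe gave 0.20. Secreted growth factors showed 10 rises and no fall among 20 (11 and 3 adjusted over the list alone; 6 rises with the slide as a block). Lif rose by 4.47 ± 0.22, the EGF receptor ligand Areg by 6.75 ± 0.35, Osm by 2.17 ± 0.20 and Vegfc by 1.88 ± 0.17 (adjusted p = 2.72e-06, and 0.114 with an estimated correlation). Of 20 p53 targets, 7 rose and 1 fell, the same adjusted over the list alone and 5 and 0 with the slide as a block. Fas rose by 2.60 ± 0.18, Gadd45a by 2.23 ± 0.18, Gdf15 by 1.82 ± 0.21 and Plk2 by 1.51 ± 0.17 (adjusted p = 1.46e-05, and 0.0598 with an estimated correlation).

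Mesenchymal and matrix genes showed 5 rises and no fall among 21, the same adjusted over the list alone, including Acta2 (2.32 ± 0.24), the urokinase Plau (1.29 ± 0.22), its receptor Plaur (1.54 ± 0.27) and Snai1 (1.77 ± 0.39), with 2 rises left with the slide as a block (adjusted p = 0.00314, and 0.0977 with an estimated correlation). Lysosome and autophagy genes showed 3 rises and 2 falls among 27, the same adjusted over the list alone. Gpnmb rose by 4.93 ± 0.24, Lamp2 by 1.05 ± 0.18 and Atg7 by 0.79 ± 0.17. Tfeb, a transcription factor for lysosome genes, fell by 1.02 (list adjusted p = 0.0153, 0.12 with an estimated correlation and 0.0518 with the slide as a block).

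Genes of oxidative phosphorylation lay lower in RAW264.7 knockdown cells, with 7 falls and no rise among 30 (8 and 0 adjusted over the list alone), such as Ndufv2 (-0.83 ± 0.19), Cox5a (-0.68 ± 0.17), Sdhb (-0.76 ± 0.19) and Cyc1 (-0.69 ± 0.19). Their adjusted p of 0.0147 became 0.509 with an estimated correlation and 0.684 after quantile normalisation, where the median lay 0.0237 above that of all genes. Ribosomal protein genes showed 4 falls and no rise among 30 (2 falls adjusted over the list alone), among them Rps3 (-0.89 ± 0.18), Rps2 (-0.81 ± 0.19) and Rpl3 (-0.64 ± 0.17), with an adjusted p of 0.00148 that became 0.534 with an estimated correlation and 0.743 after quantile normalisation, where the median lay 0.0412 above that of all genes. Of the genes named here none passed after quantile normalisation, and of the 6 besides Ndufv2 none passed with median centring. No member of either list passed on its own with the slide as a block, although camera still placed both below the other genes (adjusted p = 0.00319 and 0.00356).

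Among lipid droplet and lipolysis genes of RAW264.7 cells, 2 of 23 rose and 4 fell, with the silenced Abhd5 itself among the 4. The counts were the same adjusted over the list alone (adjusted p = 0.349 for the list), and no member passed with the slide as a block. Dgat2, which makes triacylglycerol, rose by 1.61 ± 0.31 and Hilpda, a lipid droplet protein and inhibitor of ATGL, by 1.16 ± 0.24, while the monoacylglycerol lipase Mgll fell by 0.80. Pnpla2, which encodes ATGL itself and was singled out after its values were seen, fell by 0.84 (adjusted p = 0.0235). Fatty acid oxidation genes and PPAR targets showed 4 rises and 4 falls among 24 (5 and 6 adjusted over the list alone, 1 rise and no fall with the slide as a block, adjusted p = 0.124). Cd36 and Acot1 (1.12 ± 0.22) were higher and Eci1 (-0.84 ± 0.17) and Pparg (-0.70 ± 0.17) lower. Pparg did not pass with median centring (adjusted p = 0.0639). Cd36 is also a member of the alternative activation list. Sterol and fatty acid synthesis genes showed 3 rises and 4 falls among 33, the same adjusted over the list alone and 1 rise with the slide as a block (adjusted p = 0.522). Scd1 (2.17 ± 0.26) and Me1 (1.51 ± 0.22) were higher, and Mvd (-1.03 ± 0.23) and Elovl6 (about 2-fold, adjusted p = 0.0151) lower, but Mvd did not pass with median centring (adjusted p = 0.0894). Polyamine genes showed 3 rises and 2 falls among 14 (4 and 4 adjusted over the list alone, 2 rises with the slide as a block, adjusted p = 0.301). Both arginases rose, Arg1 (4.86 ± 0.55) and Arg2 (3.62 ± 0.19).

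The remaining RAW264.7 lists did not pass. NRF2 and antioxidant genes showed 5 rises and 1 fall among 27, the same adjusted over the list alone and 3 rises with the slide as a block (adjusted p = 0.0501, but 0.000128 after quantile normalisation). The cystine transporter Slc7a11 was at least 6.08-fold higher, Nqo1 rose by 3.45 ± 0.23 and Osgin1 by 1.65 ± 0.19. Interferon-stimulated genes moved both ways, with 3 rises and 10 falls among 29 (5 and 10 adjusted over the list alone, 2 and 8 with the slide as a block, adjusted p = 0.858, with the direction higher here and lower with median centring, quantile normalisation or the slide as a block). Gbp3 rose by 2.85 ± 0.32, and Ifi44, Usp18 and Rtp4 fell by 2.83, 1.79 and 1.43. Glycolysis and hypoxia genes showed 3 rises and no fall among 25, the same adjusted over the list alone and 1 rise with the slide as a block (adjusted p = 0.0982, but 0.00397 after quantile normalisation). P4ha2 rose by 3.69 ± 0.47, Ero1a by 1.49 ± 0.23 and Vegfa by 0.82 ± 0.19. Cell cycle genes showed 1 rise, Ccne2 (1.85 ± 0.38), and 7 falls among 32 (1 and 11 adjusted over the list alone, none with the slide as a block, adjusted p = 0.0982). Of the falls, Ccnb2 (-0.83 ± 0.18) and Cdc20 (-0.78 ± 0.18) no longer passed with median centring or quantile normalisation, and Mki67 (-0.85 ± 0.19) not with median centring. NADPH oxidase genes showed 1 rise, Nox1 (3.21 ± 0.32, other probe 1.75), and 4 falls among 13, the same adjusted over the list alone and 1 rise with the slide as a block (adjusted p = 0.521). Cybb (-1.22 ± 0.23), Ncf1 (-0.89 ± 0.20) and Duox1 (-0.96 ± 0.23) fell, but Ncf1 did not pass with median centring (adjusted p = 0.0579). Wnt targets showed 1 rise, Myc (2.83 ± 0.30), and 1 fall, Lef1 (-1.81 ± 0.17), among 14 (2 and 3 adjusted over the list alone, 1 and 1 with the slide as a block, adjusted p = 0.668). Genes of the unfolded protein response showed 2 rises and 2 falls among 23, the same adjusted over the list alone and 1 fall with the slide as a block (adjusted p = 0.71). Dnajb9 (0.74 ± 0.19) and Atf3 (0.74 ± 0.20) rose and Hyou1 (-1.29 ± 0.20) fell.

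Relative to the median of all tested genes, the shift of the 9 lists called higher in RAW264.7 cells ranged from 0.394 for mesenchymal genes to 1.64 for alternative activation, and with the slide as a block from 0.278 for lysosome genes to 1.63 for alternative activation. Some lists with a camera direction of higher had a median below 0 in the scaling used: NRF2, interferon-stimulated, Wnt, glycolysis, polyamine, macrophage identity, sterol, unfolded protein and lipid droplet genes. Their medians lay above 0 with median centring, and none of the 9 passed. The sizes of Arg1, Nox1, Ccne2, Scd1, Gbp3 and Areg rest on control signals near the floor, since 1 of 3 control arrays was well above background, and those of Mmp9, Nqo1 and Snai1 in part, with 2 of 3. So does the fall of Duox1 (1 of 3), which within slide 2 was -0.605 (adjusted p = 0.0968). After normexp the changes of Arg1, Nox1, Ccne2, Scd1 and Snai1 were 3.26, 1.53, 0.70, 0.90 and 0.89. Those of Atp6v0d2, Mmp13 and Slc7a11 were 5.41, 1.95 and 1.96 on the log2 scale, smaller than the bounds given for them. Against the control of slide 2 alone that of Ccne2 was 0.94 (adjusted p = 0.0765). Of 111 genes named in RAW264.7 cells besides Abhd5, 106 passed, and 45 of these calls were lost with the slide as a block, none with a change of direction.

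**Figure D2:**
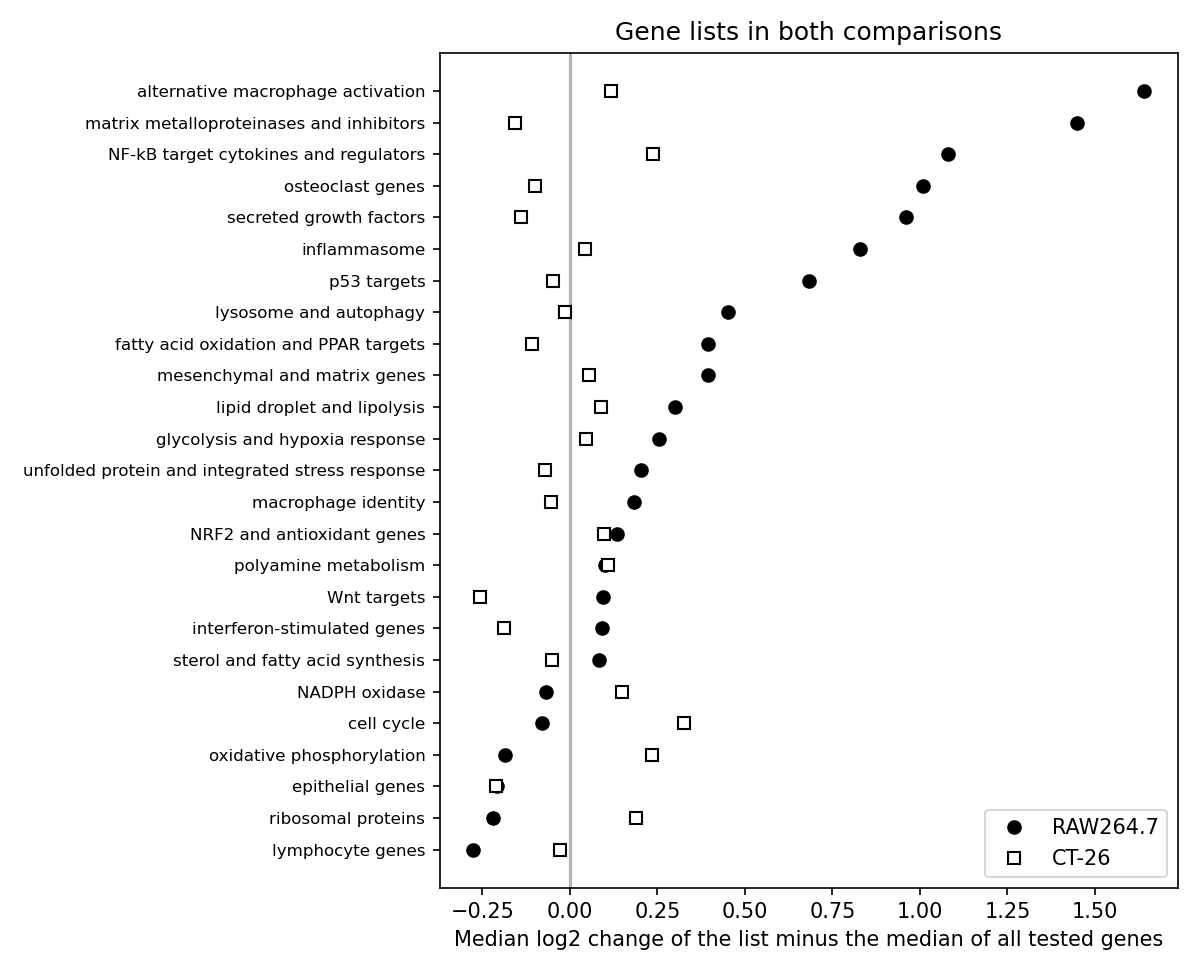
Median log2 change of each of the 25 gene lists minus the median of all tested genes, in RAW264.7 cells (filled circles) and in CT-26 cells (open squares). Alternative activation lies highest in RAW264.7 cells, at 1.64, and the cell cycle list in CT-26 cells, at 0.327; the shift of oxidative phosphorylation genes in RAW264.7 cells and of ribosomal protein genes in both lines, among others, changes sign after quantile normalisation.

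In CT-26 cells primed by knockdown macrophages, compared with those primed by control macrophages, the largest rises among genes well above background on all 6 arrays included acute phase and chemokine genes. The acute phase gene Saa3 rose by 3.60 ± 0.17 on the log2 scale (12.15-fold, adjusted p = 4.46e-05), the neutrophil chemokine Cxcl5 by 3.02 ± 0.18 (8.11-fold), the iron-siderophore carrier Lcn2 by 2.90 ± 0.17 (7.48-fold), and the protease inhibitor Slpi by 2.27 ± 0.24. Ccl2 rose by 2.34 ± 0.19 and Zmynd15 by 2.61 ± 0.17, though a second Zmynd15 probe gave 0.165. Urah, an enzyme of urate breakdown, rose by 2.36 ± 0.19, and the histone gene H2ac6, whose near-identical copies the probe may not separate, by 2.65 ± 0.40. Features without a gene symbol had been passed over, so the falls that follow are the largest among named genes well above background on all 6 arrays: C79240 (-2.03 ± 0.30), the cytochrome P450 gene Cyp2b23 (-1.94 ± 0.27), Ifi211 (-1.94 ± 0.30), the polycomb gene Pcgf2 (-1.91 ± 0.40), the heparan sulfate enzyme gene Ndst3 (-1.85 ± 0.20, but -1.08 after normexp), Ppp4r1l-ps (-1.81 ± 0.18), Cd6 (-1.78 ± 0.45) and Slurp2 (-1.75 ± 0.36). Pcgf2, Cd6 and Slurp2 did not pass after quantile normalisation (adjusted p = 0.0572, 0.0744 and 0.0568), nor Cd6 with median centring (0.056), and a second Pcgf2 probe gave 0.07.

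Detected in control-primed CT-26 cells alone were Tenm3, at least 9.01-fold lower after priming by knockdown cells, Dnm3, at least 3.66-fold, and C230029M16, at least 2.71-fold. After normexp the log2 changes of Tenm3 and Dnm3 were -1.74 and -0.661, smaller than these bounds, and C230029M16 did not pass (limma adjusted p = 0.435). Each of the 3 knockdown-primed arrays had a lower share of spots well above background (67.0%, 63.8% and 59.3%) than any of the 3 control-primed arrays, the lowest of which had 68.3%.

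Of 24995 genes tested in CT-26 cells, 1549 changed, 729 higher and 820 lower, and 602 did so by at least 2-fold (126 higher, 476 lower). The median change of all tested genes was 0.101, against 0.146 with median centring, where 1027 were higher and 657 lower, 0.0475 after quantile normalisation (620 and 678), and 0.179 after normexp (1120 and 655). At 2-fold or more falls were the larger part in each (162 and 396, 136 and 359, 89 and 255). Among all calls, the larger part also changed with the filter on detection. With only genes well above background on all arrays compared, 1149 were higher and 795 lower. In the main fit, 714 rises and 559 falls were well above background on all CT-26 arrays, with groups that did not overlap. Whether the excess of falls at 2-fold or more depends on genes near background was not tested. Without a filter on detection 41 genes passed. Leaving out 1 array gave 92 genes without control-primed replicate 3 and 275 without replicate 2, and 2949, 639 and 251 without knockdown-primed replicates 1, 2 and 3.

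NF-kB targets were the list with the smallest p in CT-26 cells as in RAW264.7 cells. In CT-26 cells 11 of 32 tested members rose and none fell (13 and 0 adjusted over the list alone), with an adjusted p of 3.44e-05 that became 0.387 with an estimated correlation. Saa3 and Lcn2 led, with the chemokines Ccl7 (2.15 ± 0.17) and Cxcl1 (2.06 ± 0.15). Cell cycle genes showed 6 rises and no fall among 32 (14 and 0 adjusted over the list alone; adjusted p = 0.000185, and 0.584 with an estimated correlation). The replication licensing gene Cdc6 rose by 1.34 ± 0.16, cyclin E1 (Ccne1) by 1.17 ± 0.19, and the helicase subunits Mcm5 and Mcm3 by 0.95 ± 0.16 and 0.70 ± 0.15.

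**Figure D3:**
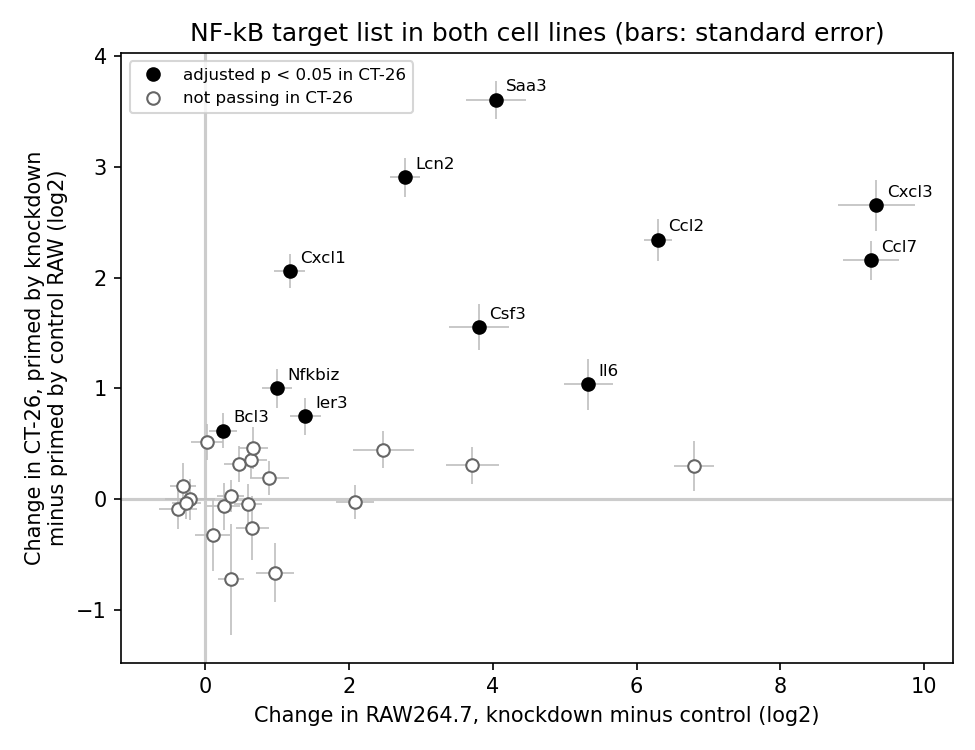
Log2 change of each NF-kB target tested in both comparisons, in RAW264.7 cells after knockdown (horizontal) and in CT-26 cells after priming by knockdown RAW264.7 cells (vertical), with standard errors. Filled points, the 11 genes past the threshold in CT-26 cells, lie between 0.62 (Bcl3) and 3.60 (Saa3) on the vertical axis.

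Of 3 other CT-26 lists past the threshold, no member passed on its own, over all genes or adjusted over the list alone. Oxidative phosphorylation genes lay higher (30 tested, median change 0.334, adjusted p = 0.00293, 0.899 with an estimated correlation and 0.357 after quantile normalisation), with Ndufa5 at 0.59 ± 0.18 and Uqcrq at 0.54 ± 0.16. Ribosomal protein genes lay higher (30 tested, median change 0.289, adjusted p = 0.0401, 0.899 with an estimated correlation), with Rps9 at 0.53 ± 0.17 and Rps7 at 0.48 ± 0.19, but lay in the other direction relative to all genes after quantile normalisation (adjusted p = 0.786). Interferon-stimulated genes lay lower (32 tested, median change -0.0883, adjusted p = 0.0278, and 0.584 with an estimated correlation), with Oasl2 at -0.72 ± 0.19, Irgm1 at -0.67 ± 0.17 and Oas2 at -0.70 ± 0.23.

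The other metabolic and signalling lists in CT-26 cells did not pass. Fatty acid oxidation genes and PPAR targets showed 3 falls and no rise among 24 (4 and 0 adjusted over the list alone; adjusted p = 0.107, but 0.0326 after quantile normalisation). Ppargc1a, a co-activator of mitochondrial genes, fell by 1.62, the dehydrogenase gene Acadl by 0.81 and Hadha by 0.62. Among lipid droplet genes 1 of 22 fell, Plin4 (-1.03 ± 0.18), the same adjusted over the list alone (adjusted p = 0.551). Among sterol and fatty acid synthesis genes 1 of 33 fell, Insig1 (-0.93 ± 0.18), likewise (adjusted p = 0.841). Of metalloproteinases and inhibitors 1 of 17 fell, Mmp13 (-0.88 ± 0.19; 2 rises and 2 falls adjusted over the list alone, adjusted p = 0.551). So did 2 of 24 secreted growth factors, Inhba (-0.70 ± 0.16) and Pdgfc (-0.63 ± 0.15; the same adjusted over the list alone, adjusted p = 0.412), and 1 of 14 Wnt targets, Sox9 (-0.95 ± 0.15; 0 rises and 3 falls adjusted over the list alone, adjusted p = 0.166). Single rises were those of Nlrp3 (1.02 ± 0.18, other probe 0.178) among 14 inflammasome genes (adjusted p = 0.49), Aen (0.84 ± 0.20) among 18 p53 targets (0.978), and Ccl17 (0.97 ± 0.15) among 12 genes of alternative activation (0.829), each 1 and 0 adjusted over the list alone. Paox rose (0.63 ± 0.16) among 13 polyamine genes (0.551; 1 and 1 adjusted over the list alone). Aen did not pass after quantile normalisation (0.65, adjusted p = 0.0848), nor Hadha, Pdgfc and Ankrd37 with median centring (adjusted p = 0.0536, 0.0543 and 0.0603). The list of NADPH oxidase genes, 10 of them tested, had an adjusted p of 0.466. Glycolysis and hypoxia genes showed 1 rise, Pfkfb3 (0.66 ± 0.16), and 1 fall, Ankrd37 (-0.79 ± 0.19), among 25 (2 and 1 adjusted over the list alone, adjusted p = 0.978). No member passed among 27 NRF2 genes (adjusted p = 0.58; Gsr at 0.65 ± 0.20), 23 genes of the unfolded protein response (0.586; Dnajc3 at 0.53 ± 0.18) or 27 lysosome and autophagy genes (0.704; Npc1 at -1.17 ± 0.33), over all genes or adjusted over the list alone. The camera direction and the sign of the median differed in CT-26 cells for sterol, glycolysis, unfolded protein, lysosome, macrophage identity, osteoclast and lymphocyte genes, none of which passed. The direction was the other one after quantile normalisation for NRF2, p53, mesenchymal, osteoclast and lymphocyte genes, and with median centring for glycolysis genes.

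The last comparison asked whether the changes in CT-26 cells resembled those in the macrophages that primed them. Across the 23381 genes tested in both, which are not independent replicates, the log2 changes had a Pearson correlation of -0.14 (-0.0554 with RAW264.7 changes taken within slide 2) and a Spearman correlation of -0.208. Even so, genes higher in both lines were more frequent than in independent lists: 72 against 46.53 (1593 and 683 calls, odds ratio 1.64, two-sided Fisher's exact p = 0.000268). Genes lower in both were less frequent, 68 against 94.91 (3585 and 619 calls, odds ratio 0.675, Fisher's exact p = 0.00184). Another 208 genes changed in opposite directions, a count for which no number under independent lists was computed. It was therefore not weighed against the shared rises. Fisher's test treats genes as independent, which they are not. Both overlaps were counted in the scaling used only. The RAW264.7 falls called there, 3834 among all tested genes, became 1414 with median centring and 280 with the slide as a block.

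The size of the change differed between the cell lines for 8620 of the 23381 genes (interaction contrast, limma), with 1972 more positive and 6648 more negative in RAW264.7 cells, and by at least 2-fold for 4900. Ctsk, the chemokine receptor Ccr1, Mmp9, Ccl7 and Areg had the largest positive differences, and Pxdn, Hspb7, Gdpd3, Hoxc6 and Igf2bp1 the largest negative ones. Ccl7 alone of these 10 also passed in CT-26 cells, where it rose by 2.15 against 9.26 in RAW264.7 cells, the latter value resting on control arrays below background. Of the 5 positive differences none had all 3 RAW264.7 control arrays well above background, so their order is uncertain. The split was 2281 and 4536 with median centring, 2361 and 4048 after quantile normalisation and 1554 and 8750 after normexp. The median difference of all genes was -0.39 in the scaling used, and -0.213, -0.141 and -0.501 in these, in that order. At 2-fold or more the split was 1524 and 3376 in the scaling used. It was 1791 and 1793 with median centring, 1698 and 1803 after quantile normalisation and 1055 and 4032 after normexp. The excess of negative differences thus depended on the scaling. With the slide as a block 2489 genes passed (963 and 1526). Cell line and slide cannot be told apart in the levels, since no slide held both lines.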

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

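The tests of the slide, as a cause and as the whole cause, and of the arrays of slide 2 alone were chosen only after the result was seen; for the test of carried-over RAW264.7 RNA the prediction came first, but the genes it used were defined after the median of the macrophage list had been seen, so 2 definitions were run.

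The macrophages and the tumour cells primed by them responded differently: for 8620 of 23381 genes the change in RAW264.7 cells differed from the change in CT-26 cells in the test of the difference itself. The largest positive differences (RAW264.7 change minus CT-26 change, log2, with SE) were those of Ctsk (10.6 ± 0.67), Ccr1 (8.25 ± 0.79), Mmp9 (7.18 ± 0.37), Ccl7 (7.10 ± 0.46) and Areg (6.94 ± 0.40). The largest negative ones were those of Pxdn (-5.16 ± 0.26), Hspb7 (-5.09 ± 0.26), Gdpd3 (-4.61 ± 0.22), Hoxc6 (-4.59 ± 0.25) and Igf2bp1 (-4.49 ± 0.23). In CT-26 cells Ccl7 rose by 2.15, while Ccr1 (-1.13, adjusted p = 0.0747) and the other 8 did not pass. Ctsk and Ccl7 had no RAW264.7 control array well above background, Ccr1 and Areg had 1 and Mmp9 had 2, so the sizes of these 5 and their order depend on signals near the floor. Other groupings of the arrays within each cell line were tried: of 100, 1, the real one, gave as many genes (8568 of those with a value on every array), and the highest other gave 5590. Every grouping that broke the real RAW264.7 groups called at most 1 gene. The draw thus could not separate the difference from the RAW264.7 change alone, and chance is not excluded for this count. The other splits that called more than 1 gene all kept the real RAW264.7 groups. Splits that broke these groups put the large RAW264.7 changes into the residual spread of the fit. The counts therefore do not show which cell line makes up the main part of the difference.

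The large RAW264.7 changes, such as those of Il1b and S100a8, were weighed against the slide, because control replicates 1 and 2 lay on slide 1 and the other 4 arrays on slide 2. Of 623 genes at least 4-fold above the slide 1 controls, 96% also lay above the slide 2 control, a single array, with a median ratio of the second change to the first of 0.861, and 97.6% lay above the median within-slide change of all genes (-0.251). Genes under 2-fold apart gave 79.1% and 0.64. Of 149 genes at least 4-fold below, 142 (95.3%) also lay below the slide 2 control, but the ratio of 0.645 was that of genes under 2-fold apart, so a part of the slide in their size stays open, and 89.3% lay below the median of all genes, short of the 90% first set for excluding it as the whole cause. With no array shared between the 2 changes and genes of like signal compared, a test added after that bound was missed, 93.8% to 96.9% of the large rises lay beyond the median of genes under 2-fold apart, against 69.8% to 78% of rises under 2-fold, and 76.6% to 91% of the large falls, against 54.1% to 60%, which argues against the slide as the whole cause of either. A copy number difference between the cell lines carrying the vectors was tested for whole chromosomes only: the largest departure of a chromosome's median from all genes was -0.126 (chromosome 12), which argues against it as the cause of changes of this size, but segments were not excluded. An effect of losing Abhd5 may explain these changes and stays open beside selection of the transfected cells or an off-target effect of the hairpin, since the labels describe no second hairpin and no rescue.

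The inflammatory genes higher in CT-26 cells, such as Saa3 and Ccl7, might come from RAW264.7 RNA carried over. Of the 11 NF-kB targets past the threshold, 10 were brighter in knockdown RAW264.7 cells than in primed CT-26 cells. The other, Cxcl1, was not, so carried-over RNA could not give its rise. The median share of such RNA that the 10 genes would need was 14.5% (from 0.0867% for Csf3 to 64.5% for Lcn2). Such a share predicted a median rise of 7.88 for 6 macrophage identity genes that were well above background on fewer than 3 control-primed CT-26 arrays. The observed median rise was 0.69 (range -0.34 to 0.94), a ratio of 0.0874. The second definition took 18 genes at least 32-fold lower in control-primed CT-26 than in RAW264.7 knockdown cells. There the prediction was 5.98 against 0.15 observed (range -0.70 to 1.23). This argues against carry-over greater in knockdown-primed than in control-primed cells as the cause of the rise of these genes as a set. Smaller shares stay open for single genes such as Csf3. An equal share carried into both CT-26 groups would raise only genes higher in knockdown than in control RAW264.7 cells. The test does not address that case. Over 27 macrophage identity genes the median level was -3.96 in control-primed CT-26 and 3.65 in control RAW264.7 cells. Of them 21 were well above background on all control-primed arrays. The dimmer knockdown-primed arrays were weighed as well. The median rise of the 11 genes, chosen by their calls in the scaling used, was 2.06 there and 2.01 after quantile normalisation, a ratio of 0.974. This argues against the dimmer arrays as the source of a rise of that size, though 9 list members passed after quantile normalisation, against 11. A response of the tumour cells to priming stays a hypothesis.

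For the counts within each cell line, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real RAW264.7 split gave 5849 genes with a value on every array and the highest other 0, and the real CT-26 split gave 1552 and the highest other 3; in each line 1 split, the real one, gave as many.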

How the results depend on the processing

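The arrays of slide 2 alone, the slide as a random block and the lists within the slide were tests chosen only after the result was seen; the other settings were planned. The number of RAW264.7 genes past the threshold, 5856, became 2561 with a 2-fold minimum, 3823 with median centring, 2671 without a detection filter (35078 genes tested), 9720 with array weights, 9207 in a fit of all 12 arrays, 1173 with the slide as a block, 1857 on slide 2 alone (1 control array, assumed to vary like the knockdown arrays) and 4720 with the slide as a random block. The CT-26 count, 1549, became 602 with a 2-fold minimum, 41 without a detection filter, 2502 for each probe on its own, 3856 with array weights, 1021 in a fit of all 12 arrays and 919 with the replicate number as a block (4841 in RAW264.7 cells). The count for the difference, 8620, became 4900 with a 2-fold minimum and 2489 with the slide as a block (7456 with the replicate block). Same-number correlations were -0.0118, 0.0111 and -0.0784 in RAW264.7 cells and -0.0982, -0.166 and -0.0263 in CT-26 cells, so the numbers were not taken as pairs. The CT-26 values and block count hold for the scanner files' order; in the deposited table's order the pairs would give 0.0782, 0.151 and -0.0263. Leaving out 1 array gave 1704 to 7389 genes in RAW264.7 cells, 92 to 2949 in CT-26 cells and 5680 to 9539 for the difference. Abhd5 in RAW264.7 cells ranged from -1.44 to -1.16 (adjusted p at most 0.0241) and was -1.24 with the slide as a block (adjusted p = 0.0541). In CT-26 cells it ranged from -0.0204 to 0.12, and was -0.24 for the mean of its probes. The correlation between the lines ranged from -0.182 to -0.0529. Reversed were Loxl2 in CT-26 cells for the mean of its probes (-1.12, adjusted p = 0.0314), whose probes disagree, Muc1 in RAW264.7 cells after normexp (-0.31, adjusted p = 0.214), and the ribosomal list in CT-26 cells after quantile normalisation (adjusted p = 0.786). Fewer arrays, more or fewer genes tested or a fold minimum account for some changes by construction; otherwise the cause was not tested. Of the 5856 RAW264.7 genes 1113 also passed with the slide as a block, and of the 1549 CT-26 genes 1114 after quantile normalisation. The slide block could not be fitted within CT-26, since all 6 arrays lay on 1 slide. Signal over background limits what is seen: a gene not well above background on all arrays of at least 1 group was not tested.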

Other observations

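In both cell lines 27 genes rose at least 2-fold, a set chosen after its values were seen and not tested for any function. For acute phase genes among them the RAW264.7 and CT-26 changes were 4.04 and 3.60 for Saa3, 2.15 and 2.16 for Saa1, 2.92 and 2.09 for haptoglobin (Hp), 3.02 and 1.05 for ceruloplasmin (Cp), and 2.78 and 2.90 for Lcn2. Among secreted signals they were 6.30 and 2.34 for Ccl2, 9.26 and 2.15 for Ccl7, 1.18 and 2.06 for Cxcl1, 9.33 and 2.65 for Cxcl3, 3.81 and 1.56 for Csf3, and 5.33 and 1.04 for Il6. The iron transporter gene Slc11a1 (1.02 and 1.89) and the phospholipase gene Pla1a (4.29 and 1.32) also belonged to the set. The other members were U90926, Slpi, Urah, Serpinb2, Ppbp, Nlrp3, Bik, Cbr2, Cela1, Fndc7, Ly6c1, Prl2c1, Prl2c5 and Rmi2. Some of these sizes rest on control signals near the floor: in RAW264.7 cells Ccl7 and Cxcl3 were well above background on no control array, Il6 on 1, and Hp and Cxcl1 on 2, and in CT-26 cells Csf3 and Cxcl3 on 2 control-primed arrays.

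Macrophage identity genes kept the cell lines apart: their median level over 27 genes was 3.65 in control RAW264.7 cells and -3.96 in control-primed CT-26 cells, where 21 of 27 were still well above background on all arrays. In RAW264.7 cells 5 of 27 rose and 3 fell after knockdown (5 and 6 adjusted over the list alone; adjusted p = 0.0831, but 0.00412 after quantile normalisation). The Fc receptor Fcgr3 rose by 2.92 ± 0.20, Adgre1 (F4/80) by 2.86 ± 0.24 and Mpeg1 by 2.77 ± 0.24, and the chemokine receptor Cx3cr1 fell by 1.31; with the slide as a block 3 rose. In CT-26 cells Trem2 rose (1.11 ± 0.18) and Cd68 fell (-0.83 ± 0.15) among 21 such genes (1 and 3 adjusted over the list alone, adjusted p = 0.69). Of 13 osteoclast genes in CT-26 cells none passed, over all genes or over the list alone (adjusted p = 0.866).

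Among lymphocyte genes, 0 of 11 rose and 3 fell in RAW264.7 cells, Ebf1, Cd79b (-1.50 ± 0.39) and Cd79a (-0.87 ± 0.26), with 0 and 6 adjusted over the list alone (adjusted p = 0.0982). With the slide as a block none passed, and Cd79b and Cd79a passed neither with median centring (adjusted p = 0.0866 and 0.0776) nor after quantile normalisation. Cd79a was well above background on 1 of 3 control arrays. In CT-26 cells Cd79b rose (0.98 ± 0.14), the single member of 11 past the threshold (1 and 1 adjusted over the list alone, adjusted p = 0.825). Among epithelial genes of RAW264.7 cells 1 of 15 rose, Muc1, and 2 fell, Elf3 (about 4-fold lower, adjusted p = 0.00106) and Tjp3 (-1.23 ± 0.18). The counts were the same adjusted over the list alone (camera adjusted p = 0.336). With the slide as a block 0 rises and 1 fall passed. The rise called for Muc1 is left without a size: no control array was well above background, and its knockdown mean of -5.94 lay below the lowest such signal on control arrays 1 and 2 (-4.81). After normexp it was -0.31. None of 14 passed in CT-26 cells, over all genes or over the list alone (adjusted p = 0.385). Of 27 mesenchymal and matrix genes in CT-26 cells 1 rose, the matrix protein Thbs1 (1.86 ± 0.17), and 1 fell, Tgfbi (-1.41 ± 0.22), the same adjusted over the list alone (adjusted p = 0.58).

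Of the 6 CT-26 columns of the deposited values, 5 held the values of another replicate of the same group. The group comparisons do not change with such an exchange within a group, and with those values in place of the scanner files 5288 RAW264.7 and 1478 CT-26 genes passed.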
